A study of Mus musculus with 12 samples.

How the data were processed

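RNA was measured in colonic organoids, epithelial crypts grown in a gel matrix as a culture enriched in stem cells, from 3 wild-type and 3 Vdr-knockout mice. Vdr encodes the vitamin D receptor, and calcitriol is the hormone that binds it. Per the labels, the culture of each mouse was split between ethanol vehicle and calcitriol at 100 nM, given again every 48 h, and 100 ng of RNA was labelled with 1 dye. The series' design text gives 72 h of treatment and the sample descriptions give 62 h, so the duration is uncertain. The result is 12 Agilent arrays in 4 groups of 3.

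Per the file headers, the deposited values are spot intensities on a linear scale, extracted with Feature Extraction 11.5.1.1. In the processed intensity the background was subtracted, a spatial trend was removed and low values were set to a small positive floor, and nothing was normalized between arrays. The files also hold the raw median intensity of each spot and of its local background, per the file headers. The probe annotation of the array design is on the mouse build mm9, per the file headers. The submitters' processing notes name Agilent Feature Extraction and give no statistical method.

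Control spots and spots marked as outliers by the extraction software were left out. The processed intensity was taken to log2, the 75th percentile of each array was subtracted, and spots of 1 probe were averaged. Levels below are on this scale. Of 55681 probes, 28026 could be given a gene symbol, through accessions in the file matched to a RefSeq table on GRCm38.p6. That table was used for names and for which genes neighbour each other. A transcript without a symbol below is one without such a match. The other 27655 include 16194 probes for chromosome regions, and 1770 with a RefSeq accession found no match. After 163 probes with missing values were dropped, 55518 remained, and 33410 were well above background on all 3 arrays of at least 1 group. The probe with the highest mean level stood for each gene, which gave 24245 genes, 14906 with a symbol and 9339 without.

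All genes were tested with limma 3.58.1 in R 4.3.3, in a fit of the 4 group means on all 12 arrays with a variance trend and 2-sided moderated tests. P values were adjusted by the Benjamini-Hochberg method over the 24245 genes, with a threshold of 0.05. The 5 comparisons were calcitriol against vehicle in each genotype, the difference between these effects, and knockout against wild type under each treatment. For gene lists, camera was run with a preset correlation of 0.01 and again with an estimated correlation, over 31 of 32 lists with at least 5 measured genes, 880 of whose 897 genes were on the array. A gene not above background on any array of its lower group has a fold given as "at least". This is the higher group's mean against the lower group's mean of, per array, the larger of its own signal and the lowest signal among probes above background.

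The tests, the alternatives, the lists and the rule for named genes were fixed before the data were examined, except where a later choice is stated. The rule took, among called genes that went the same way in all 3 mice or whose groups did not overlap, and that were above background on all arrays of the higher group, the 12 largest rises and 12 largest falls. Unnamed transcripts and sex-linked genes were excluded. Where under 5 passed, up to 5 genes by smallest p were given as values that did not pass, with up to 4 members of each list and a fixed set of vitamin D, stem cell and differentiation genes.

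The replicate number marks the mouse within a genotype, so vehicle and calcitriol arrays of 1 number come from the same animal. Deviations from the group means correlated across genes at 0.57, 0.32 and 0.32 for the wild-type mice and at 0.25, 0.59 and 0.10 for the knockout mice. Mouse was therefore used as a block in a second fit. Between genotypes a number marks different animals of 1 labelled sex and age. There, deviations of same-numbered arrays correlated at 0.64, 0.13 and 0.40 in vehicle and at 0.41, 0.40 and 0.34 in calcitriol, and the number was the block.

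The arrays lay on 3 slides of 2, 3 and 7 arrays, and each slide had its own scan number. The smallest held 2 knockout vehicle arrays. The next held 2 wild-type vehicle arrays and 1 knockout calcitriol array. The largest held the 3 wild-type calcitriol arrays, 2 knockout calcitriol arrays and 1 vehicle array of each genotype, so slide and treatment overlap strongly. Only wild-type mouse 3 had both arrays on 1 slide.

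On data simulated with the comparison in wild type, the fit recovered 26% of 50 genes changed by 1 on the log2 scale, 84% of those changed by 2 and 98% of those changed by 4, with 1 false call among 108. With mouse as a block it recovered 56%, 98% and 100%, with 6 false calls among 137. For the genotypes in calcitriol, 16 of 127 simulated calls were false in the 12-array fit, which takes the 2 arrays of a mouse as independent, and 3 of 93 with only the 6 arrays compared. With the block these were 58 of 172 and 6 of 75, the last a fit added after the data were seen. Simulated slides were not part of these data, nor was an effect shared by same-numbered mice of the 2 genotypes.

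Alternatives covered background correction by normexp on the median intensities, since the files hold no mean spot intensity, quantile normalization, scaling to the median, the filter on dim probes, the choice of probe, the variance trend, array weights, the mouse and slide blocks, and leaving out each array and each replicate number. The share of spots above background was 55.0% to 72.8% per array, and 3 arrays per group limit the precision of every value.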

Results

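The data were 12 arrays of colonic organoids, 3 for each combination of genotype (wild type or Vdr knockout) and treatment (ethanol vehicle or calcitriol at 100 nM). The 75th percentile of the processed signal was 580.6 to 790.5 per array. The vehicle array of wild-type mouse 2 stood apart at low signal: 72.8% of its spots were well above background against 55.0% to 66.4% on the other 11, and its median signal was 89.9 against 24.7 to 56.9. Ddx3y, a Y-linked gene, lay at 0.82 to 0.99 on the 4 arrays of replicate 2, which are labelled female, and at -7.96 to -6.62 on the other 8, which include the 4 labelled male. The sex labels of replicates 1 and 2 are therefore contradicted in both genotypes, and only 1 alternative, which kept replicates 2 and 3 for their label, uses them.

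Vdr, the receptor gene targeted in the knockout, was measured first as a check of the genotype labels. Its mean level was 1.83 ± 0.43 in wild-type vehicle and 1.25 ± 0.18 in wild-type calcitriol (SD, n = 3), against 0.24 ± 0.30 in knockout vehicle and 0.15 ± 0.42 in knockout calcitriol. The 2 genotypes did not overlap, with the lowest wild-type array at 1.06 and the highest knockout array at 0.61. The difference in vehicle was -1.59 (SE 0.26) and did not pass over all genes (limma adjusted p = 0.329), but passed with the replicate number as a block (adjusted p = 0.0137). In calcitriol it was -1.11 (SE 0.26, adjusted p = 0.25, and 0.0079 with the block). These blocked calls of Vdr ended in vehicle without knockout mouse 1, 2 or 3 (0.155, 0.323 and 0.0855) or wild-type mouse 2 or 3 (0.309 and 0.31), and in calcitriol without knockout mouse 1 or 2 (0.0892 and 0.0982) or wild-type mouse 2 (0.0583). The Vdr probe was well above background on all 12 arrays, and whether it lies in the deleted part of the gene is not known here, so a residual signal does not speak against the labels.

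Calcitriol against vehicle in wild-type organoids shows which genes the hormone changes where its receptor is present, and genes of vitamin D breakdown and calcium transport were among those that rose. Cyp24a1, which encodes the enzyme that degrades calcitriol, rose by 11.99 on the log2 scale (SE 0.72, n = 3 and 3, adjusted p = 1.76e-05), from vehicle cultures where it was above background on 1 of 3 arrays. With the background level in place of the dim arrays, the rise was at least 1570-fold. S100g, which encodes an intracellular calcium-binding protein, rose by 7.49 (SE 0.17, adjusted p = 4.32e-10), a 180.1-fold change. Trpv6, the apical calcium channel, rose by 4.46 (SE 0.59, adjusted p = 0.0107), and Atp2b1, the calcium pump of the plasma membrane, rose by 1.63 (SE 0.14, adjusted p = 0.000291). Slc30a10, a manganese exporter, was higher by 6.39 (SE 1.18) without passing (adjusted p = 0.0855), and passed with mouse as a block (adjusted p = 9.31e-05).

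**Figure D1:**
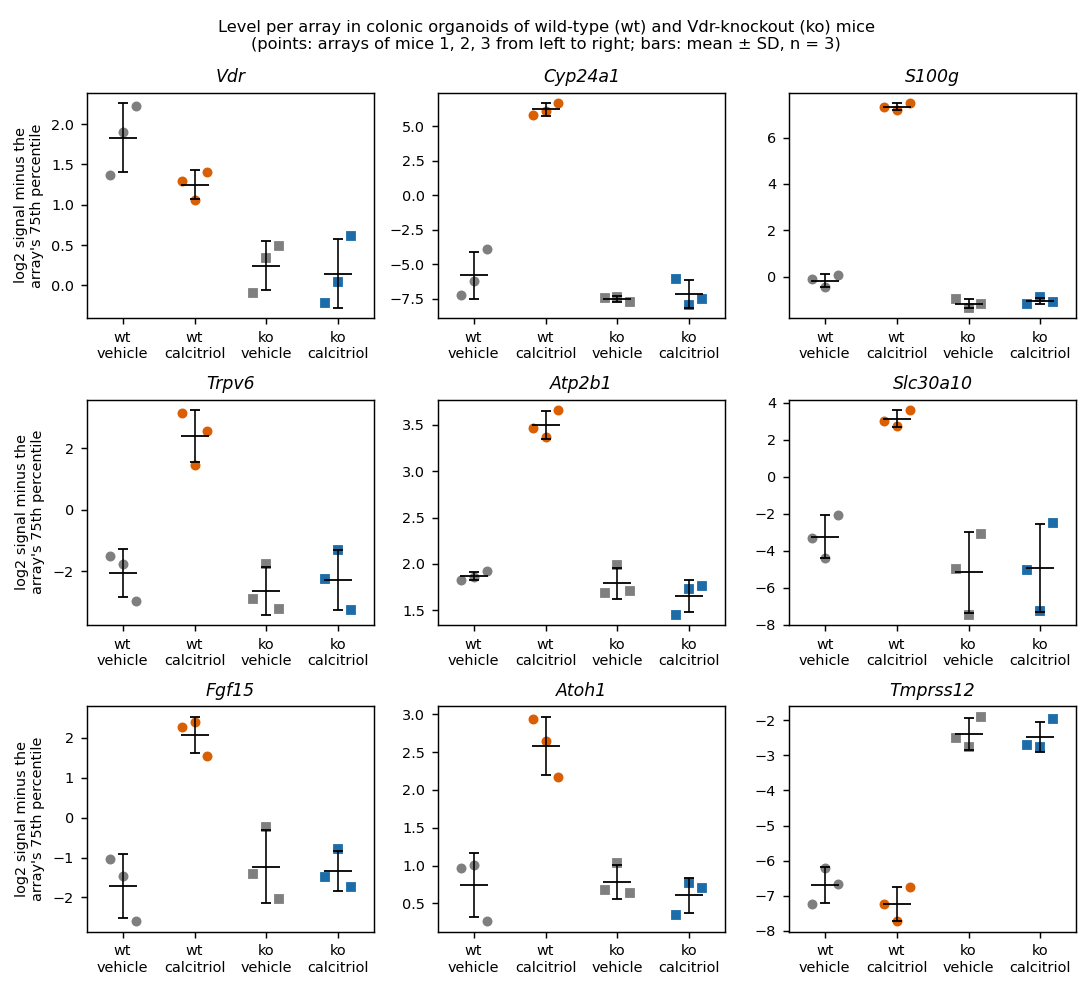
Level of 9 genes on each array, as log2 signal minus the array's 75th percentile, in wild-type (wt) and Vdr-knockout (ko) organoids; points are arrays of mice 1, 2 and 3 from left to right and bars are mean ± SD (n = 3). S100g stood at 7.33 in wild-type calcitriol against -0.17 in wild-type vehicle, -1.16 in knockout vehicle and -1.04 in knockout calcitriol.

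Genes outside calcium handling also rose in wild type. Fgf15, a gut hormone that restrains bile acid synthesis in the liver, rose by 3.78 (SE 0.49, adjusted p = 0.00971), and Atoh1, the transcription factor that commits crypt cells to secretory fates, rose by 1.84 (SE 0.24, adjusted p = 0.0107). Cbln1, a secreted protein known from synapses, rose by at least 12.9-fold (adjusted p = 0.024), since none of the 3 vehicle arrays had it above background. Klk11, a secreted serine protease, rose by 4.53 (SE 0.65) and Pla2g7, which inactivates platelet-activating factor, by 4.51 (SE 0.66), with adjusted p of 0.0176 and 0.0178. C2cd4b (3.76, SE 0.39), the class I antigen gene H2-Q1 (3.71, SE 0.50), the matrix protein gene Spon2 (3.68, SE 0.57), the alcohol dehydrogenase gene Adh6a (2.95, SE 0.35) and Trim47 (2.77, SE 0.32) rose with adjusted p between 0.00169 and 0.0255. Ms4a18 fell by 1.45 (SE 0.22, adjusted p = 0.024). Mgp, which encodes an inhibitor of calcification, was higher by 5.29 (SE 1.02) without passing (adjusted p = 0.0978), and passed with mouse as a block (adjusted p = 0.000366).

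Of 24245 genes, limma called 38 in wild type, 36 higher and 2 lower with calcitriol, 35 of them by at least 2-fold. The fit with mouse as a block called 227, 157 higher and 70 lower, 37 of them also called without it. Without wild-type mouse 1, 2 or 3 the blocked count was 56, 47 and 84, with 4, 4 and 15 lower. Among the 70, the acute-phase gene Saa2 fell by 2.71 (adjusted p = 0.000464 with the block, 0.988 without), Ttr, which carries thyroid hormone and retinol, by 2.01 (0.000633 and 0.342) and the trypsin inhibitor gene Spink1 by 1.84 (0.00131 and 0.988), and these 3 blocked calls were kept when any 1 wild-type mouse was left out. Lgr5 and Ascl2, genes of crypt stem cells, differed by -0.33 (SE 0.20) and -0.59 (SE 0.32), both with adjusted p = 0.988. With the block, Ascl2 passed (adjusted p = 0.0348, but 0.246 and 0.278 without mouse 1 or 2) and Lgr5 did not (0.12).

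Slide and single arrays bear on these calls. The 1 wild-type vehicle array on the largest slide is that of mouse 3, which had a raised floor. Every comparison within that slide that uses wild-type vehicle rests on it. The fit with slide as a block called 8 genes, and 3 were called among the 7 arrays of the largest slide, where wild-type vehicle has 1 array, assumed to vary like the other groups. S100g stood at 7.36 (adjusted p = 6.32e-07) and 7.26 (0.00018) in these fits, Cyp24a1 at 10.89 (0.00104) and 10.11 (0.0318), Atp2b1 at 1.66 (0.0169) and 1.58 (0.153), Trpv6 at 4.41 (0.237) and 5.35 (0.132), Fgf15 at 4.03 (0.0867) and 4.68 (0.0613), and Atoh1 at 2.13 (0.0672) and 2.32 (0.195). The count was 18, 14 and 20 without the wild-type calcitriol array of mouse 1, 2 or 3, and 24 without the vehicle array of mouse 3. Cyp24a1, S100g, C2cd4b, Adh6a, Trim47 and Atp2b1 kept their call when any 1 array was left out. The 9 other named calls each ended without at least 1 array. The calcitriol array of mouse 1 ended those of Trpv6 (adjusted p = 0.0605), H2-Q1 (0.0632), Klk11 (0.119), Pla2g7 (0.119), Spon2 (0.0632), Fgf15 (0.0542), Atoh1 (0.0605) and Cbln1 (0.191). In that order their rises without it were still 4.09, 3.59, 4.095, 4.14, 2.99, 3.68, 1.66 and 4.39. The calcitriol array of mouse 2 ended the calls of Klk11 (0.148), Pla2g7 (0.133), Fgf15 (0.0686), Atoh1 (0.076), Spon2 (0.136), Cbln1 (0.161) and Ms4a18 (0.168), and that of mouse 3 ended those of Trpv6 (0.053), H2-Q1 (0.0559), Cbln1 (0.0518) and Ms4a18 (0.122). Vehicle arrays of mouse 1, 2 or 3 ended those of Spon2 (0.0599, 0.0721 and 0.124) and Ms4a18 (0.0941, 0.0743 and 0.0614), and those of mouse 1 or 3 ended Cbln1 (0.0931 and 0.128) and Pla2g7 (0.0625 and 0.0992).

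By list, the vitamin D response and calcium transport genes were higher as sets in wild type. Of 28 measured vitamin D response genes 4 rose, Cyp24a1, S100g, Trpv6 and Atp2b1, and 5 adjusted over the list alone. The list's median was 0.10 and its mean 1.11, so a few members carried it (camera adjusted p = 6.71e-05, and adjusted p = 0.015 with an estimated correlation). Of 26 calcium, phosphate and ion transport genes 3 rose, S100g, Trpv6 and Atp2b1, which both lists hold, and 4 adjusted over the list alone (median 0.05, mean 0.80, adjusted p = 9.01e-05, and adjusted p = 0.015 with an estimated correlation). Their means were 1.09 and 0.80 with slide as a block and 1.16 and 0.73 within the largest slide. Both lists passed with mouse as a block and the preset correlation (0.00213 and 0.000614) but not with an estimated one (adjusted p = 0.424 and adjusted p = 0.338 with an estimated correlation).

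Markers of goblet and deep crypt secretory cells were higher, with 20 of 29 members above 0 and a median of 0.19 (adjusted p = 0.00045, but adjusted p = 0.905 with an estimated correlation). Atoh1 was the 1 called member, 2 were called adjusted over the list alone, and 6 rose and 1 fell with mouse as a block. The members that passed with the block include the pentraxin gene Mptx1 (3.04, adjusted p = 0.0159 with the block and 0.314 without), the goblet cell genes Bcas1 (1.21, 0.00447 and 0.648) and Rep15 (0.92, 0.00675 and 0.795). Their blocked calls ended for Mptx1 without mouse 1 or 3 (0.124 and 0.112), for Bcas1 without mouse 2 (0.0933) and for Rep15 without mouse 1 or 2 (0.0946 and 0.0889). The list's median was 0.40 within the largest slide and 0.36 with slide as a block. In knockout it was -0.01, but 0.30 within the largest slide and 0.19 with slide as a block. NF-kB targets and chemokines were lower as a set, with 3 of 26 above 0 and a median of -0.27 (adjusted p = 0.0387, but adjusted p = 0.905 with an estimated correlation). None of them was called without the block, also adjusted over the list alone, with Csf2 at least 3.3-fold lower (above background on 2 vehicle and 0 calcitriol arrays, adjusted p = 0.82) and Ccl2 at -1.30 (SE 0.65, adjusted p = 0.988). With mouse as a block the 1 called member was higher, Nfkbia, which encodes an inhibitor of NF-kB (0.47, adjusted p = 0.0433, but 0.137, 0.323 and 0.222 without mouse 1, 2 or 3), and 1 rose and 4 fell adjusted over the list alone. The list did not pass without the vehicle array of wild-type mouse 2 (0.151). It stood at 0.000436 with mouse as a block (adjusted p = 0.621 with an estimated correlation) and at 0.0709 with slide as a block, where its median was -0.28, and the median within the largest slide was -0.17. The vitamin D median was -0.04 under normexp and the NF-kB median 0.24 under scaling to the median, which shifts the median of all genes from -0.03 to 0.48. Against all genes both kept their side.

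3 lists passed with mouse as a block and not without it, of which 2 also passed with slide as a block, enteroendocrine (0.00903) and interferon genes (0.00142). Enteroendocrine cell genes had a median of 0.20 (camera adjusted p = 0.366, and 0.0218 with the block, where adjusted p = 0.623 with an estimated correlation). The enteroendocrine median was -0.06 under normexp, or 0.01 over all genes, 0.27 with slide as a block and 0.62 within the largest slide, where it was 0.57 in knockout. Interferon and antigen presentation genes had 0.10 (0.162, and 0.0204 with the block, where adjusted p = 0.623 with an estimated correlation). Nrf2 antioxidant genes had -0.15 (0.521, and 0.0414 with the block, where adjusted p = 0.629 with an estimated correlation). Interferon genes had 0.22 within the largest slide, where knockout had 0.30, and 0.01 under normexp, or 0.08 over all genes. The Nrf2 list had -0.07 within that slide and -0.02 with slide as a block (0.933). Neurog3, which starts the enteroendocrine fate, was higher by 1.12 (SE 0.23, adjusted p = 0.137, and 0.00381 with the block, but 0.0546 and 0.0638 without mouse 1 or 2).

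**Figure D2:**
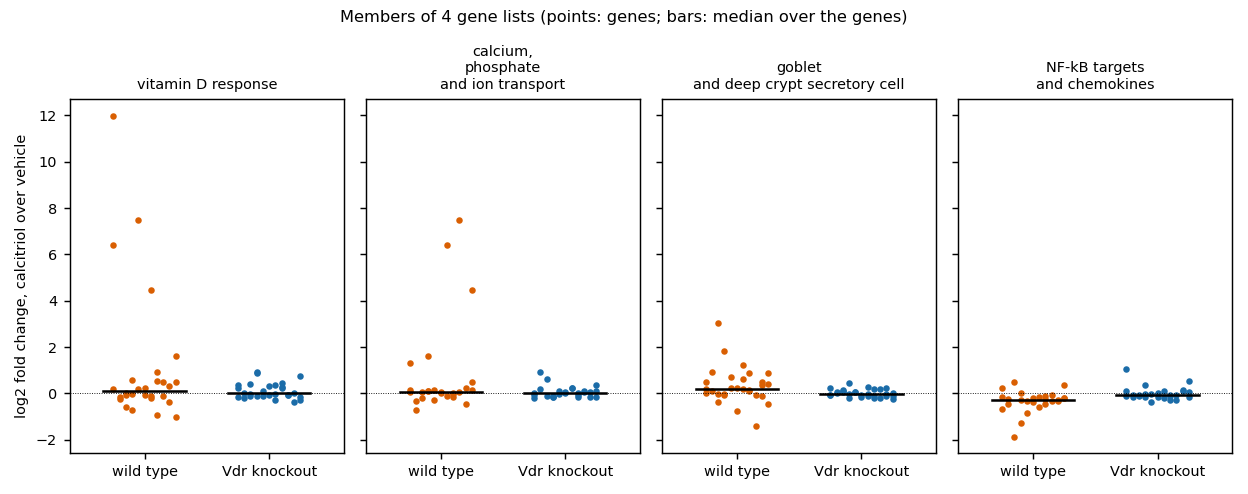
Log2 fold change, calcitriol over vehicle, of the members of 4 gene lists in wild-type and Vdr-knockout organoids (n = 3 and 3 arrays per genotype); points are genes and bars are medians over the genes. In wild type the vitamin D response list has its median at 0.10 and its mean at 1.11, with Cyp24a1 at 11.99 and S100g at 7.49 as its highest points.

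Calcitriol against vehicle in knockout organoids is the control for effects of the hormone that do not need the receptor. Cyp24a1 was above background on none of the 6 knockout arrays, and S100g differed by 0.12 (SE 0.17), Atp2b1 by -0.14 (SE 0.14), Trpv6 by 0.35 (SE 0.59) and Slc30a10 by 0.24 (SE 1.18). The genes with the smallest p included the odorant receptor genes Olfr94 (2.06, SE 0.51) and Olfr97 (1.64, SE 0.36) among the higher ones. Lower with calcitriol were the growth regulator Myc (-1.46, SE 0.50) and the carboxylesterase gene Ces2h (at least 3.2-fold, with no calcitriol array above background), all 4 with adjusted p = 0.864. limma called 0 genes, with 1363 at unadjusted p under 0.05, and 0 with mouse as a block, with 1966. Uniform p values would give 1212.2. On simulated data, however, 1.74% of unchanged genes had p under 0.05 without the block and 4.65% with it. The count of 1363 is therefore not shown to be near chance. Leaving out any 1 array kept the count at 0, but without replicate 3 it was 126, all higher. Without replicate 3 every remaining mouse had its vehicle and calcitriol arrays on different slides.

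5 lists passed in knockout with the preset correlation, and 0 with an estimated one. All 14 immune cell markers were above 0, with a median of 0.59 (camera adjusted p = 0.00106, but adjusted p = 0.538 with an estimated correlation), and 12 of 16 tuft cell markers, with a median of 0.49 (adjusted p = 0.0227, but adjusted p = 0.538 with an estimated correlation). Posterior Hox genes (-0.15) and adhesion and tight junction genes (-0.08) were lower, each at adjusted p = 0.0194 and adjusted p = 0.538 with an estimated correlation. The p53 target median was -0.11 (adjusted p = 0.0194, but adjusted p = 0.68 with an estimated correlation). The immune list stood at 0.0286 and the tuft list at 0.362 with slide as a block, with medians of 0.53 and 0.21, and within the largest slide the medians were 0.60 and 0.34. Under normexp both medians were 0.16. Both lists are dim, with mean levels of -2.17 and -2.26. Dim fibroblast (-2.74) and endothelial, neural and glial genes (-1.32) had medians of 0.32 and 0.33 without passing, but enteroendocrine genes (-1.56) had -0.02. Spots above background were 55.0%, 55.7% and 66.4% in knockout vehicle mice 1, 2 and 3, and 62.3%, 64.2% and 62.8% in calcitriol. Random lists of like level were not drawn here, so an effect of low signal stays open. Hox, adhesion and p53 genes did not pass with slide as a block (0.69, 0.362 and 0.235; medians -0.12, -0.08 and -0.06), and their medians within the largest slide were -0.08, -0.06 and -0.01. With mouse as a block, crypt stem cell genes (median -0.10, 0.0775 without and 0.0132 with it, where adjusted p = 0.739 with an estimated correlation) and proliferation genes (-0.08, 0.0661 and 0.0379, where adjusted p = 0.739 with an estimated correlation) passed too. These 2 did not pass with slide as a block (0.235 and 0.126), with medians of -0.12 and -0.13 there and -0.16 and -0.22 within the largest slide. No member of the 7 lists that passed was called, also adjusted over the list alone.

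The difference between the effects in the 2 genotypes tests whether the response needs Vdr. It passed for Cyp24a1 (adjusted p = 0.00116), with no size given as the gene was not well above background in knockout. The difference was 7.38 for S100g (SE 0.24, adjusted p = 2.97e-08) and 1.77 for Atp2b1 (SE 0.20, adjusted p = 0.00582). Cebpd, a transcription factor of differentiation and inflammation, differed by 2.30 (SE 0.32, adjusted p = 0.0407), and Gdpd5, a phosphodiesterase gene, by 2.14 (SE 0.23, adjusted p = 0.00582). limma called 7 genes, all with the larger effect in wild type, of which 2 have no gene symbol, and 57 with mouse as a block, 53 of them higher. The block also let pass Slc30a10 (6.16, adjusted p = 0.00168), Mgp (5.17, 0.00513), Trpv6 (4.11, 0.035) and Fgf15 (3.88, 0.00278), which stood at 1, 1, 0.339 and 0.156 without it. The blocked count was 21, 24 and 31 without wild-type mouse 1, 2 or 3 and 25, 22 and 62 without knockout mouse 1, 2 or 3. The blocked call ended for Mgp without wild-type mouse 1 (0.0524), and for Trpv6 without wild-type mouse 1 or 3 (0.192 and 0.0632) or knockout mouse 1 or 2 (0.102 and 0.209). The 36 genes that rose in wild type had a median change of 2.13 there and of 0 in knockout, from -0.45 to 0.95. All 36 passed the difference adjusted over these genes alone, which is not independent evidence, as they were chosen on the wild-type arrays.

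Cebpd lost its call without any 1 array other than the vehicle array of wild-type mouse 1. For mice 1, 2 and 3 its adjusted p was 0.135, 0.113 and 0.13 without the wild-type calcitriol array, 0.0948, 0.0805 and 0.0908 without the knockout vehicle array and 0.0696, 0.154 and 0.131 without the knockout calcitriol array. Without wild-type vehicle mouse 2 or 3 it was 0.143 and 0.0899. The other 4 named calls were kept. The fit with slide as a block called 1 gene, S100g, which stood at 7.17 (adjusted p = 8.86e-05), and Cyp24a1 stood at adjusted p = 0.216, Atp2b1 at 1.74 (0.903), Gdpd5 at 1.84 (0.903) and Cebpd at 2.30 (0.903). Within the largest slide, where each genotype has 1 vehicle array, assumed to vary like the calcitriol arrays, 2 genes were called, with S100g at 7.12 (0.00374), Cyp24a1 at adjusted p = 0.514, Atp2b1 at 1.70 (0.625), Gdpd5 at 1.88 (0.625) and Cebpd at 2.43 (0.6). Vitamin D response and calcium transport genes differed as sets (both adjusted p = 9.21e-06, and adjusted p = 0.00806 with an estimated correlation). With mouse as a block both stood at 0.000153, and did not pass with an estimated one (adjusted p = 0.248 and adjusted p = 0.245 with an estimated correlation). Their means were 1.00 and 0.73, the first with Cyp24a1 at its fitted value, with 5 and 4 members called adjusted over the list alone. Goblet and secretory genes had a median of 0.23 (adjusted p = 7.32e-05, but adjusted p = 0.67 with an estimated correlation), with 1 called adjusted over the list alone. The first 2 lists stood at 0.0293 and 0.0136 with slide as a block (means 0.92 and 0.85, and 0.96 and 0.82 within the largest slide) and the goblet list at 0.083 (medians 0.17 and 0.35). 3 more lists passed with mouse as a block, enteroendocrine (0.0771 without and 0.00495 with it, where adjusted p = 0.78 with an estimated correlation), interferon (0.0771 and 0.0242, where adjusted p = 0.78 with an estimated correlation) and NF-kB genes (0.466 and 0.0451, where adjusted p = 0.802 with an estimated correlation). None of the 3 passed with slide as a block (0.817, 0.639 and 0.355). The enteroendocrine median was 0.22, and -0.15 with slide as a block, 0.02 within the largest slide and -0.07 under normexp, or 0.01 over all genes.

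**Figure D3:**
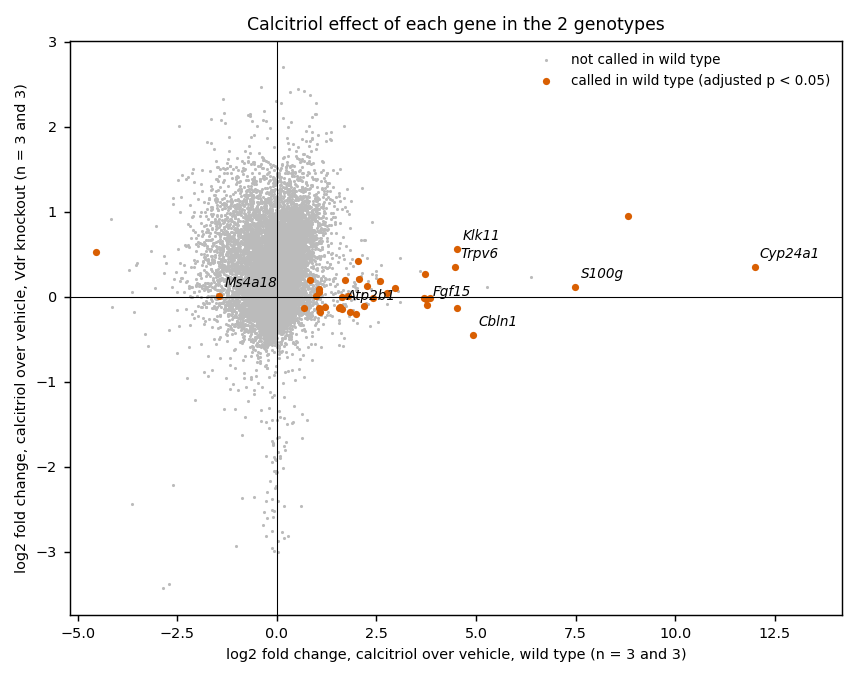
Log2 fold change, calcitriol over vehicle, of 24245 genes in wild-type organoids (horizontal axis) and Vdr-knockout organoids (vertical axis), n = 3 and 3 arrays per genotype; coloured points are the 38 genes called in wild type. The 36 that rose in wild type lie between -0.45 and 0.95 in knockout.

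Knockout against wild type under calcitriol shows what the cultures without the receptor lack while the hormone is present. Cyp24a1 was at least 3810-fold lower in knockout (adjusted p = 5.17e-06), S100g lower by -8.37 on the log2 scale (SE 0.17, adjusted p = 1.18e-10), Slc30a10 by -8.08 (SE 1.18, adjusted p = 0.0142) and Mgp by -7.03 (SE 1.02, adjusted p = 0.014). Trpv6 (-4.67, SE 0.59, adjusted p = 0.00508), Atoh1 (-1.98, SE 0.24, adjusted p = 0.00473) and the alcohol dehydrogenase gene Adh1 (-1.58, SE 0.21, adjusted p = 0.00713) were lower too. Mgll, which encodes a monoacylglycerol lipase, was lower by -4.35 (SE 0.67, adjusted p = 0.0199), and its 2 other probes gave -1.92 and -4.21 without passing. Tmprss12, a membrane serine protease gene, was at least 9.18-fold higher in knockout (adjusted p = 0.000484), and Ms4a18 (1.64, SE 0.22, adjusted p = 0.00793) and Rtn4rl1, a receptor gene of the Nogo family (1.62, SE 0.27, adjusted p = 0.0365), were higher.

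In all, limma called 50 genes, 3 higher and 47 lower in knockout, and 245 with the replicate number as a block, 78 higher and 167 lower. The blocked count was 113, 94 and 152 without wild-type mouse 1, 2 or 3 and 120, 85 and 208 without knockout mouse 1, 2 or 3. The 6 arrays of this comparison alone gave 50 without the block and 122 with it. In 1 simulated data set the 12-array fits made more false calls than the fits of 6 arrays. Same-numbered mice shared no effect there, unlike in these data, so how far the 12-array fits call too many genes here is uncertain. The count was 31, 26 and 33 without the wild-type calcitriol array of mouse 1, 2 or 3, and 33 and 25 without the knockout calcitriol array of mouse 1 or 3. Of 18 named calls 9 were kept without any 1 array. Slc30a10 lost its call without wild-type calcitriol mouse 1, 2 or 3 (adjusted p = 0.0735, 0.0751 and 0.0821) or knockout calcitriol mouse 1 or 2 (0.0707 and 0.0511), and Mgp without wild-type mouse 1 or 2 (0.067 and 0.0751) or knockout mouse 2 or 3 (0.0739 and 0.0748) of that treatment. Mgll lost it without wild-type calcitriol mouse 1 or 2 (0.138 and 0.159) or knockout calcitriol mouse 1, 2 or 3 (0.0667, 0.118 and 0.097). Adh1, Ms4a18, H2-Q1 and Spon2 lost it without knockout calcitriol mouse 3 (0.0504, 0.0504, 0.0504 and 0.0623), Ms4a18 also without wild-type calcitriol mouse 2 or 3 (0.0633 and 0.0515), and Klk11 without wild-type calcitriol mouse 1 or 2 (0.105 and 0.116) or knockout calcitriol mouse 1 or 3 (0.0581 and 0.0856). Rtn4rl1 lost it without wild-type calcitriol mouse 1, 2 or 3 (0.0572, 0.226 and 0.183), knockout calcitriol mouse 1 or 3 (0.179 and 0.191), wild-type vehicle mouse 1 or 2 (0.051 and 0.0588) or knockout vehicle mouse 3 (0.0667). The fit with slide as a block called 35 genes, and that within the largest slide 15. There S100g stood at -8.30 and -8.35 (adjusted p = 5.32e-08 and 1.99e-05), and Trpv6 at -4.64 and -4.17 (0.0398 and 0.108). Cyp24a1 (4.8e-05 and 0.00135) and Tmprss12 (0.0068 and 0.029) passed in both, with no size given. Of the 36 genes risen in wild type, 34 were also lower in knockout, against 0.0698 for independent lists. The wild-type calcitriol arrays enter both comparisons, so part of the excess may come from them. In 20 simulations without effects 0 genes passed in both, which says little where hardly any gene passes, and the 36 and 47 genes of smallest p in these directions shared 5.7 on average and 9 at most.

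By list, 10 passed, and the vitamin D response was lower in knockout under calcitriol, with 5 of 28 members called and 6 adjusted over the list alone (median -0.04, mean -1.33 with Cyp24a1 at its fitted value, adjusted p = 2.4e-07, and adjusted p = 0.00376 with an estimated correlation). Calcium transport had 4 of 26 called and 5 adjusted over the list alone (mean -0.95, adjusted p = 3.31e-07, and adjusted p = 0.00376 with an estimated correlation). The goblet and secretory median was -0.17, with 1 called and 4 adjusted over the list alone (adjusted p = 0.000151, but adjusted p = 0.401 with an estimated correlation). Interferon and antigen presentation genes stood at -0.14, with 0 called and 1 adjusted over the list alone (adjusted p = 0.00104, but adjusted p = 0.401 with an estimated correlation). Higher in knockout were Nrf2 antioxidant genes (median 0.17, adjusted p = 6.94e-05, but adjusted p = 0.401 with an estimated correlation) and immediate early genes (0.28, adjusted p = 0.000428, but adjusted p = 0.401 with an estimated correlation), the latter with 1 called adjusted over the list alone. So were ribosomal protein genes, with 35 of 37 above 0 and a median of 0.14 (adjusted p = 4.92e-05, but adjusted p = 0.621 with an estimated correlation), which was 0.01 under quantile normalization. Hypoxia genes had 0.16 (adjusted p = 0.00119, but adjusted p = 0.644 with an estimated correlation) and proliferation genes 0.16 (adjusted p = 0.00266, but adjusted p = 0.778 with an estimated correlation). Fibroblast and smooth muscle genes were lower at -0.17 (adjusted p = 0.0217, but adjusted p = 0.401 with an estimated correlation), with Mgp as the 1 called member and 4 of 10 above 0, and had 0.03 under normexp, or -0.03 over all genes. Means of the first 2 lists were -1.32 and -0.95 with slide as a block, and -1.28 and -0.98 within the largest slide. In the same order the goblet median was -0.22 and -0.17, the interferon median -0.17 and -0.11, the Nrf2 median 0.16 and 0.15, the immediate early median 0.23 and 0.27, the ribosomal median 0.20 and 0.19, the hypoxia median 0.16 and 0.14, the proliferation median 0.16 and 0.10 and the fibroblast median -0.04 and -0.02. All 10 passed with slide as a block. With the replicate number as a block 3 lists passed that had not, Paneth cell genes (median -0.24, 0.116 without and 0.0449 with it, where adjusted p = 0.563 with an estimated correlation), adhesion genes (0.11, 0.0557 and 0.0197, where adjusted p = 0.595 with an estimated correlation) and NF-kB genes (0.10, 0.118 and 0.0215, where adjusted p = 0.516 with an estimated correlation). With slide as a block they stood at 0.0395, 0.585 and 0.374, with medians of -0.22, 0.04 and 0.14, and -0.35, 0.03 and 0.16 within the largest slide. The Paneth median was -0.04 under normexp.

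Knockout against wild type in vehicle shows the effect of the genotype without added hormone. Tmprss12 was at least 4.81-fold higher in knockout (SE 0.44 on the log2 scale, adjusted p = 0.0128) and was above background on 0 of the 3 wild-type arrays. S100g was lower by -0.99 (SE 0.17) without passing (adjusted p = 0.329), and Lima1, which encodes an actin-binding protein, by -0.71 (SE 0.14, adjusted p = 0.568). Tmprss12 was the 1 gene limma called, with 2097 at unadjusted p under 0.05, and 4 were called with the replicate number as a block, Vdr and Tmprss12 among them, with 0 to 2 when any 1 mouse was left out. With the block and only the arrays compared, 0% of the calls were higher in knockout, so Tmprss12 was not among them. Its call without the block ended without knockout vehicle mouse 1, 2 or 3 (adjusted p = 0.13, 0.0931 and 0.0868), knockout calcitriol mouse 1 or 2 (0.0557 and 0.052) or wild-type vehicle mouse 3 (0.0887). It did not pass with slide as a block (0.403) or within the largest slide (0.448), where 1 array stands against 1, each assumed to vary like the calcitriol arrays.

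14 lists passed in vehicle with the preset correlation and none with an estimated one, where adjusted p was 0.377 to 0.698. Ribosomal protein genes were higher in knockout in 37 of 37 cases, with a median of 0.16 (adjusted p = 5.6e-08, but adjusted p = 0.469 with an estimated correlation). Their median was 0 under quantile normalization. ER stress genes stood at 0.15 (adjusted p = 0.000593, but adjusted p = 0.455 with an estimated correlation) and hypoxia and glycolysis genes at 0.17 (adjusted p = 0.000507, but adjusted p = 0.635 with an estimated correlation). The hypoxia list did not pass without the vehicle array of wild-type mouse 2 (0.147). Lower were markers of immune cells at -0.65 (adjusted p = 0.00295, but adjusted p = 0.455 with an estimated correlation) and of tuft cells at -0.49 (adjusted p = 0.00292, but adjusted p = 0.388 with an estimated correlation). Fibroblast and smooth muscle genes were at -0.53 (adjusted p = 0.0177, but adjusted p = 0.388 with an estimated correlation). Without the vehicle array of wild-type mouse 2 the immune median was -0.37. No member of the 14 lists was called without the block, also adjusted over the list alone. With it 2 fibroblast genes and 1 tuft gene were lower and 1 ER stress and 1 immediate early gene higher adjusted over the list alone. Dim genes had a median difference of -0.82 below a level of -4 and -0.36 from -4 to -2. Without the vehicle array of wild-type mouse 2 these were -0.42 and -0.23, with that of mouse 3, also raised at low signal, still included. Bright genes were slightly higher in knockout, by 0.06 from a level of 2 to 4 and by 0.10 above 4. The ribosomal, hypoxia and ER stress lists had mean levels of 8.17, 5.29 and 3.89, and the higher lists were not compared with random lists of like level. Scaling to the median shifted all genes from -0.05 to 0.73 and the 3 lower medians to 0.13, 0.28 and 0.25, but over all genes these stayed at -0.60, -0.45 and -0.48. Quantile normalization put the fibroblast median at 0.15, or 0.12 over all genes. The immune, tuft and fibroblast lists stood at 0.0156, 0.156 and 0.177 with slide as a block (medians -0.56, -0.44 and -0.49), and within the largest slide the medians were -0.42, -0.43 and -0.40. Ribosomal, ER stress and hypoxia medians were 0.18, 0.43 and 0.34 with slide as a block and 0.14, 0.30 and 0.31 within the largest slide. 8 more lists were higher, again only with the preset correlation. They were proliferation (0.15, adjusted p = 0.000773, but adjusted p = 0.698 with an estimated correlation), adhesion (0.12, adjusted p = 0.000722, but adjusted p = 0.388 with an estimated correlation), Nrf2 (0.18, adjusted p = 0.00109, but adjusted p = 0.455 with an estimated correlation) and immediate early genes (0.14, adjusted p = 0.000773, but adjusted p = 0.455 with an estimated correlation). Crypt stem cell genes had 0.10 (adjusted p = 0.0126, but adjusted p = 0.377 with an estimated correlation) and BMP and TGF-beta genes 0.12 (adjusted p = 0.0351, but adjusted p = 0.388 with an estimated correlation). Enteroendocrine genes had 0.31 and p53 targets 0.05 (both adjusted p = 0.021, but adjusted p = 0.698 with an estimated correlation). BMP and p53 lists did not pass without the vehicle array of wild-type mouse 2 (0.0873 and 0.414), and the enteroendocrine median was -0.16 with slide as a block (0.979). With slide as a block immediate early, crypt stem cell, BMP and p53 lists did not pass either (0.165, 0.0666, 0.0604 and 0.156).

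With the replicate number as a block 2 more lists passed in vehicle, regenerative and fetal-like genes (median 0.07, 0.112 without and 0.0499 with it, where adjusted p = 0.416 with an estimated correlation) and fatty acid oxidation genes (0.11, 0.067 and 0.0273, where adjusted p = 0.416 with an estimated correlation). With slide as a block they stood at 0.165 and 0.237, with medians of -0.18 and 0.19.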

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

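The tests of slide, of calcitriol acting without the receptor, of slide for the immune list and of lists without 1 vehicle array were chosen only after the results were seen, and the tests of a raised floor, of RNA of other cells and of other splits of the arrays were set before.

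The calcitriol effect differed between the genotypes in 7 genes by limma's test of the difference itself. It passed for Cyp24a1, which degrades calcitriol (adjusted p = 0.00116), and for a transcript without a gene symbol (0.00582), with no size given, as neither was well above background in knockout vehicle. It was larger in wild type by 7.38 on the log2 scale for the calcium-binding protein gene S100g and by 1.77 for the calcium pump gene Atp2b1. Cebpd, a transcription factor gene, differed by 2.30, the phosphodiesterase gene Gdpd5 by 2.14, and another transcript without a symbol by 1.85. Of 100 splits drawn from 200 within the genotypes, 12 gave as many genes, with up to 16 in the others. All 12, the real split among them, kept the real treatment groups of wild type, the 11 others moved only knockout arrays, and the 88 that broke these groups gave 0 genes. Of 17 splits that parted the arrays of all 6 mice, 4 gave as many, with up to 9 in the others. Splits that moved only knockout arrays kept the wild-type response, and limma called 0 genes in knockout. These shares therefore cannot tell chance from a difference between the genotypes, and no conclusion is drawn from them.

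6 lists differed between the genotypes in their calcitriol effect by camera with the preset correlation. Vitamin D response and calcium transport genes had larger effects in wild type (both adjusted p = 9.21e-06, and adjusted p = 0.00806 with an estimated correlation), as had goblet and secretory genes (adjusted p = 7.32e-05, but adjusted p = 0.67 with an estimated correlation, and 0.083 with slide as a block). ER stress genes had a median difference of 0.07 (adjusted p = 0.0278, but adjusted p = 0.895 with an estimated correlation), and of 0.45 with slide as a block (3.82e-05) and 0.36 within the largest slide. Tuft cell genes differed the other way with a median of -0.57 (adjusted p = 0.000705, but adjusted p = 0.356 with an estimated correlation), and did not pass with slide as a block (0.083). Immune cell genes had -0.55 (adjusted p = 0.0278, but adjusted p = 0.895 with an estimated correlation), and did not pass with mouse as a block (0.0606). The tuft and immune medians were -0.29 and -0.16 under quantile normalization. Scaling to the median, which shifts all genes to 0.74, put them at 0.23 and 0.25, but over all genes they stayed at -0.51 and -0.49.

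With 3 arrays against 3, 10 splits are too few for a share under 0.05. In wild type the real split called 38 genes and was the 1 split with as many, the highest other being 0. For the genotypes in calcitriol it called 50, again 1 split, the highest other being 0. In knockout all 10 splits gave 0. For the genotypes in vehicle 3 splits gave at least the 1 gene of the real split. The highest, 1263 genes, set wild-type vehicle mouse 1 with knockout vehicle mice 1 and 2, the arrays with the fewest spots above background, which points to a structure of the samples, and the other splits that parted 3 pairs gave 0.

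Ddx3y, a Y-linked gene outside the comparisons, had its lowest level of replicate 2, labelled female, at 0.82. A dim spike-in control had a signal of 92.0 on the vehicle array of wild-type mouse 2 against 3.35 to 25.2 on the other 11.

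Calcitriol effects went together across 11480 bright genes in wild-type mice 1 and 2 and knockout mice 1 and 2, at a mean correlation of 0.613 (0.471 to 0.731). Over all genes most of these correlations were weaker, from -0.12 to 0.648. In these 4 mice the calcitriol array lay on the largest slide and the vehicle array on another, a different one for each genotype. Calcitriol acting without the receptor would also reach knockout mouse 3, whose vehicle array lay on the largest slide and calcitriol array on another, but that mouse correlated with knockout 1 and 2 at -0.283. This does not exclude it, as it is 1 mouse and a slide effect alone could turn its correlation below 0. Slide stays open too, since the mean correlation of wild-type mouse 3, on 1 slide, and knockout mouse 3 with the 4 was -0.167. Singly, knockout mouse 3 stood at -0.306 and wild-type mouse 3 at -0.029. The latter correlated with wild-type mice 1 and 2 at 0.168 and 0.143, and with knockout mice 1 and 2 at -0.189 and -0.237. Slide may therefore account for much of what both genotypes shared. A day or person of culture that went with the slides was not tested, genes are not independent replicates, and within 1 slide S100g and Cyp24a1 were higher by 7.26 and 10.11 against 1 wild-type vehicle array, which had both above background and is assumed to vary like the other groups.

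Tuft, fibroblast and immune genes were lower in knockout vehicle, at -0.49, -0.53 and -0.65. A raised floor of wild-type vehicle arrays would leave them inside the range of random lists of like level. It did so for 2 of 3, at percentiles 3.7 and 15.9, with the immune list below the range at 0.9. Without the vehicle array of wild-type mouse 2, which stood apart at low signal, the tuft and fibroblast lists lay below at 0.2 and 1.8. Their medians were -0.48 and -0.53 there, so that array alone did not set them, and the immune list lay inside at 4.2. The vehicle array of wild-type mouse 3 had a raised floor too. Without it the tuft and immune lists lay below at 1.6 and 0.3, and the fibroblast list inside at 8.2. These 2 arrays were not left out together. Without 1 of the 6 vehicle arrays at a time, 3 fits left all 3 lists inside, each with both of these arrays kept. Which lists lay outside thus changed with 1 array, which keeps the raised floor open. RNA of other cells in wild-type vehicle cultures stays open too, as 1 of the 2 lists of other cells lay below the range and both lay inside in these 3 fits. Of 14 immune genes 1 was above 0, Cd68 at 0.17, and Ptprc was at least 2.49-fold lower. Slide, for the immune list, may also contribute, since the list lay above genes of like level on 6 of the 7 arrays of the largest slide and on 0 of the 5 others. The exception was the 1 knockout vehicle array of that slide, at -0.21, against 0.35 for its 1 wild-type vehicle array. A difference between the genotypes stays open as untested.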

How the results depend on the processing

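None of the 39 named calls changed direction under the alternatives that measured them. These held 25 of the 39 with probes above background on all arrays and 16 with only bright genes, and the fit of every probe was not compared gene by gene. All 39 were kept with mouse or replicate number as a block, with normexp and with array weights, 38 with quantile normalization and 33 with scaling to the median, 18 with slide as a block and 9 within the largest slide, and 17, 8 and 15 without replicate 1, 2 or 3. Where a value below differs, the cause was not tested, except where fewer arrays or genes enter. Signal over background limits dim genes.

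Counts are of called genes for wild type (38), knockout (0), their difference (7), genotypes in vehicle (1) and genotypes in calcitriol (50). For wild type they were 76 with scaling to the median, 95 with array weights, 20 with only the arrays compared, 8 with slide as a block, 3 within the largest slide, where lone arrays are assumed to vary like the other groups, and 13 with replicates 2 and 3, kept for their contradicted label. For the difference they were 11 with normexp, 12 with quantile normalization, 27 with scaling to the median, 15 with every probe, 17 with array weights, 1 with slide as a block and 2 within the largest slide. For vehicle they were 2 with scaling to the median and with array weights, 3 without the variance trend, and 0 with probes above background on all arrays, only the arrays compared, slide as a block, the largest slide or replicates 2 and 3. For calcitriol they were 119 with array weights, 15 within the largest slide and 18 with replicates 2 and 3. Higher calls were 80.4% of the total in wild type with normexp against 94.7%, 75.8% with array weights, 69.2% with the block and 72.1% with it as a random block, and 88.9% of the difference with scaling to the median against 100%. In calcitriol they were 18.5% with array weights, 31.8% with the block and 7.4% with mouse as a random block, against 6%. Scaling to the median moved the median of all genes to 0.48, -0.26, 0.74 and 0.73 in the first 4 comparisons, and no filter to -0.16, -0.27 and -0.31 in wild type, the difference and vehicle.

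With mouse or number as a block the counts were 227, 0, 57, 4 and 245, and as a random block 165 in wild type and 38 in the difference. With slide and the replicate block together they were 126, 51, 71, 122 and 275. For wild type, knockout and their difference the block was mouse, which leaves 2 degrees of freedom. There the wild-type effect rests on the pair of mouse 3. The knockout effect is the pair of knockout mouse 3 with a slide shift taken from the wild-type pairs, so these counts carry little weight. For the genotypes the block was the replicate number, which leaves more degrees of freedom. Vdr in vehicle passed with the block (-1.59) and with slide and block (-1.65). It kept 37 of the 38 calls in wild type and all calls in the other comparisons, and 1 transcript without a gene symbol lost its call (0.0197 without and 0.0581 with it). The further genes in these counts passed only with the block, and most of them are not named. The block changed no other list than those given beside the results.

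Leaving out 1 array or 1 replicate number gave 1 to 96 in wild type, 0 to 126 in knockout, 1 to 8 in the difference, 0 to 1 in vehicle and 7 to 56 in calcitriol. Wild type had 13, 1 and 96 without replicate 1, 2 and 3.

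Alternatives chosen after seeing the data were these. An offset of 64 gave 63 in wild type and 14 in the difference, and only bright genes 20 in wild type, 0 in vehicle and 23 in calcitriol. The replicate block gave 229, 57 and 122 (wild type, difference, calcitriol) with only the arrays compared, where Vdr stood at -1.59, and 47, 24, 2 and 94 (wild type, difference, vehicle, calcitriol) without wild-type mouse 2. With the offset the block gave 274, 67, 3 and 250, with Vdr at -1.50, and with bright genes 148, 38, 2 and 163, with Vdr at -1.59.

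Lists that passed were 4, 5, 6, 14 and 10 in the order above, and 2, 0, 2, 0 and 2 with an estimated correlation. In wild type 7 passed with mouse as a block, with slide as a block and without the vehicle array of mouse 2. With slide as a block 2 passed in knockout and 7 in vehicle. ER stress genes passed by camera only with slide as a block in wild type (0.00142, median 0.12) and in knockout (0.00172, median -0.31). So did tuft genes in wild type (0.0496, median -0.39). The correlation of effects between the genotypes across genes was 0.068, and 0.178 with normexp, 0.201 with quantile normalization and -0.032 with slide as a block. Over 11480 bright genes it was 0.364.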

Other observations

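The tests of genes around Vdr and the fits without 1 mouse were chosen only after the result was seen.

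Markers of mature colon cells and of division were not called in wild-type organoids given calcitriol without the block. The mucin gene Muc2 differed by 0.34 (SE 0.22, limma adjusted p = 0.99), the differentiation keratin gene Krt20 by 0.33 (SE 0.23, adjusted p = 0.994), the carbonic anhydrase gene Car1 by 0.24 (SE 0.21, adjusted p = 0.996) and the division marker Mki67 by -0.02 (SE 0.20, adjusted p = 1). The chloride exchanger gene Slc26a3 stood at -0.62 (SE 0.33, adjusted p = 0.988) and the enteroendocrine granule gene Chga at 0.52 (SE 0.55, adjusted p = 1). Of 41 absorptive colonocyte genes 0 were called, with a median of -0.24 (camera adjusted p = 0.628), 2 rose adjusted over the list alone, and with mouse as a block 3 rose, or 5 with 10 lower adjusted over the list alone. The 39 proliferation genes had a median of -0.08 (adjusted p = 0.564).

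With mouse as a block, single genes of enzyme and defence groups passed in wild type that had not without it. The intestinal phosphatase gene Alpi rose by 1.22 (adjusted p = 0.0143 with the block, 0.285 without), the lectin gene Itln1 by 2.37 (0.000344 and 0.342) and Adh1 by 1.08 (0.00376 and 0.0978). The sulfotransferase gene Sult1a1 fell by 1.45 (0.0143 and 0.988), the glutathione transferase gene Gsta3 by 1.05 (0.00204 and 0.988) and the bacterial lipoprotein receptor gene Tlr2 by 0.66 (0.0204 and 0.0837). Without wild-type mouse 1, 2 or 3 the blocked call ended for Alpi (0.0723, 0.16 and 0.105) and Tlr2 (0.151, 0.193 and 0.11), and without mouse 1 or 2 for Adh1 (0.0546 and 0.0789) and Sult1a1 (0.119 and 0.152). These lists did not pass as sets, with xenobiotic genes at a median of -0.05 (adjusted p = 0.829, and 0.783 with the block) and antimicrobial genes at -0.22 (adjusted p = 0.564, and 0.166 with the block).

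Genes within 100 genes of Vdr separated the genotypes on all 12 arrays more often than genes elsewhere. Of 152 measured genes within 100 genes of Vdr on either side, 5 did so. Hdac7 (0.42 in vehicle), Slc48a1 (-0.36) and Rpap3 (-0.33) lay at -1, -2 and -5 in gene order from Vdr. Lima1 (-0.71) and Tmprss12 (at least 4.81-fold higher) lay at 64 and 69. Only Tmprss12 was called, and the others had limma adjusted p = 0.568 in vehicle. In 17416 other windows of as many genes at most 3 did so, with a median of 0. Neighbouring windows share most of their genes, so these windows are far from independent. Over all 14331 measured coding genes 59 separated them, and chance gives 0.216% of genes for 12 independent arrays and up to 10% if the 2 arrays of a mouse go together. A loss of the receptor acting on genes wherever they lie would not be expected to gather 5 around Vdr. That argues only weakly against it as the source of these 5. The windows overlap, the test was chosen after the result was seen, and Tmprss12 was already the called gene in vehicle. A segment around the targeted gene that differs between the 2 lines is a candidate explanation, since 100% of the other windows held fewer, and a probe mismatch within it or an effect of the altered allele on its neighbours stays open.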
